A study of Mus musculus with 2 samples.

How the data were processed

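The series holds 2 single-cell RNA libraries from wild-type mouse thymus, prepared with 10x 3' chemistry. The DN library was sorted as live cells without surface CD3, CD4, CD8, TCRβ, TCRδ, CD19, CD11b, NK1.1, GR1 or Ter119. The DN1 library was sorted with the same exclusions and as CD44-positive and CD25-negative. The design text also names γδ T cells, for which the deposit has no library, so they were not analysed.

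The deposited matrices hold UMI counts per gene and cell barcode, made by the authors with Cell Ranger on the mm10 build, with no version stated and no normalization. Other deposited files hold the gene identifiers and the barcodes, a unit other than counts. How barcodes were called as cells was not stated. Of 27998 gene IDs in the tables, 27645 were found in the reference name table, and 56 symbols were carried by more than 1 ID. Coordinates are GRCm38 (mm10) and were taken from GENCODE by gene ID. TCR genes and the immunoglobulin genes Ighm, Igkc and Iglc2 are not in the tables.

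The DN library held 3336 barcodes with 34619998 UMIs, a median of 9001 per barcode. The DN1 library held 3187 barcodes with 28978597 UMIs, a median of 7988. Barcodes with under 500 genes or over 10% mitochondrial UMIs were left out. So were doublets called per library by Scrublet in scanpy 1.11.5 with exact neighbours, 50 in DN and 37 in DN1. This kept 3144 DN cells with 33338926 UMIs and 3134 DN1 cells with 28462072 UMIs.

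Each group has 1 library, so no test was made, no p-value is given and no spread between animals is known. Genes were summed over cells and scaled to UMIs per 1000000 UMIs of the library or class (CPM). Intervals are at 95%. Those of CPM (Poisson), ratios of CPM or shares (conditional binomial) and shares of cells (Clopper-Pearson) are exact. Those of list medians are quantiles of 1000 Poisson resamples of the counts. Those of median UMI counts relative to the library are quantiles of 1000 resamples of cells. Ratios combined over clusters used Mantel-Haenszel weights. Intervals and floors cover counting error only, or for median UMI counts the spread over cells. The log2 ratio of DN1 over DN had 0.5 count added on both sides. A gene with no UMI in one library is given as a bound against a floor of 3 counts over that library's cells, and a level or share of 0 in a group of cells with the limit that 3 counts would give.

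Gene lists and cell type markers were fixed before the data were examined. A list's members needed at least 10 UMIs over both libraries, which 13430 genes had. Each list is described by its median log2 ratio, by the members at least 2-fold higher or lower, and by the percentile of the median among 10000 random lists of equal size matched on expression. Named genes followed a fixed rule. For the whole libraries it took the 12 highest and 12 lowest log2 ratios among genes with at least 50 CPM in the higher library, without mitochondrial, ribosomal protein and receptor segment genes, and all genes of the sort. For each list it took up to 4 members with at least 30 UMIs, 2 from each end. Within a class it took the 5 highest and 5 lowest with at least 100 CPM. Per class it took IL-17-type genes with at least 30 UMIs. Genes outside this rule are named as such.

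Both libraries were clustered together without the genes of the sort: library-size normalization to 10000, log, 2000 variable genes, scaling with values limited to 10, 30 principal components, 15 neighbours and Leiden at resolution 1. A cluster's candidate class was the one with the largest share of its markers detected in at least 10% of cells and at least 2-fold above the other cells, with at least 3 such markers. The class became the name if a marker was among the cluster's 10 leading genes, or at least 3 leading genes were stress or interferon genes, or at least 50% of the markers were detected at a median of at least 0.5 of their level in the class's best cluster, and no other class had more markers among the leading genes. The markers were fixed beforehand, but these naming conditions were set after the clusters were seen. Clusters without a candidate class, or that did not meet these conditions together, are called unnamed and described by their leading genes. A class was compared between libraries only with at least 50 cells in each. For shares of cells with a UMI of 1 gene, each cell was thinned to 2500 UMIs, which left out 28 DN1 cells below that depth and no DN cell.

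The steps were tested on simulated data made from these libraries. Exact intervals held the true ratio for 95.5% of 13430 genes, and genes simulated at log2 changes of 1 and -1 gave medians of 0.99 and -0.98. Of unchanged random lists, 3.33% fell outside percentiles 2.5 to 97.5. Of 450 simulated cells, 84.9% received the class they were made with when only the markers were raised, and 100% when 200 further genes per class were raised. These cells were NK or NKT-like, plasmacytoid dendritic cell-like or without raised markers, in equal numbers and at equal depth. Naming of small or similar classes, such as γδ T-like cells, was not simulated.

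The alternatives tried were every barcode; a stricter cell filter (at most 5% mitochondrial UMIs and at least 1000 genes); doublets kept; TMM factors from edgeR 4.0.16 in R 4.3.3; cells weighted equally; list members with at least 50 UMIs; 5 counts added; resolutions 0.5 and 2; genes of the sort left in; cell-cycle genes left out; 15 components; thinned cells; and only progenitor-like cells. Further alternatives were added after the data were seen. They left out the IL-17-type and γδ genes, the stress genes or the top 3% of doublet scores before clustering, left out progenitor-like cells with an Il2ra UMI or with a Krt8 UMI or at least 10 Cd74 UMIs, used clusters 7 and 10 alone, or counted thinned cells. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9 was used.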

Results

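Transcripts of single thymocytes were counted in 2 sorted populations of wild-type mouse thymus: double-negative cells, which lack the coreceptors CD4 and CD8 (DN, 1 library of 3144 kept cells), and their CD44-positive CD25-negative subset (DN1, 1 library of 3134 kept cells). Both sorts excluded cells with surface CD3, TCRβ or TCRδ and cells of other blood lineages. Kept cells held 33338926 UMIs in DN, with a median of 9498 per cell, and 28462072 in DN1, with a median of 7981. With 1 library per group there was no replicate check, so differences describe these libraries alone. The series title names thymic TCRδ-positive cells, and the comparison asks which cells and genes the DN1 gate holds relative to all DN cells, and where genes of γδ T cells appear.

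The libraries carried the transcripts that their gates select. Cd44 (ENSMUSG00000005087, chromosome 2, 102811141 to 102901665), the gene of the adhesion receptor used to gate DN1 cells, was at 65.1 CPM in DN1 and 2.31 CPM in DN, a ratio of 28.2 (22.4 to 35.9). Il2ra (ENSMUSG00000026770, chromosome 2, 11642807 to 11693193), which encodes CD25, was at 6.57 CPM in DN1 and 141 CPM in DN, 21.5-fold (18.6 to 25) higher in DN. Of the 11 measured genes of the excluded surface markers, 6 were at least 2-fold lower in DN1 and 5 at least 2-fold higher. The CD3 genes Cd3g, Cd3e and Cd3d were 15.4-fold, 14-fold and 10.1-fold higher in DN, at 1874, 503 and 824 CPM. Cd8a, Ly6c1 and Cd8b1 were also higher in DN, by 4.27-fold, 3.99-fold and 2.43-fold. Klrb1c, the gene of NK1.1, was 51.3-fold (37.5 to 72.1) higher in DN1, Ly6c2 was 47.0-fold (36.2 to 62.0) higher and Cd4 3.46-fold (2.05 to 6.06) higher. Itgam and Cd19 had 1 and 2 UMIs in DN, with ratios of 157 (27.7 to 6245) and 9.96 (2.36 to 88.8).

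DN1 cells expressed the genes of early progenitors, and DN cells the genes of T lineage commitment and of the pre-TCR stage. All 16 progenitor genes were at least 2-fold higher in DN1, with a median log2 ratio of 4.19 (3.97 to 4.42) at percentile 100 of random lists. Among them, the growth factor receptor gene Flt3 (chromosome 5, 147330741 to 147400489) was 78.3-fold higher (52.0 to 124) and the haematopoietic factor gene Lmo2 45.2-fold (32.5 to 64.8), while Gfi1b and Cd93 were 3.92-fold and 4.67-fold higher. Of 16 T lineage commitment genes, 13 were at least 2-fold lower in DN1, with a median of -2.30 (-2.36 to -2.23) at percentile 0. Bcl11b (chromosome 12, 107910403 to 108003602), a transcription factor needed for commitment, was 29.9-fold (26.7 to 33.6) higher in DN, and the Wnt-pathway factor gene Lef1 20.9-fold (18.4 to 23.7). Gata3 was 1.72-fold higher in DN, and Cd27 was 1.62-fold higher in DN1. Of 12 DN3 and pre-TCR genes, 8 were at least 2-fold lower in DN1 and 1 higher, with a median of -1.79 (-1.94 to -1.66) at percentile 0. Ptcra (chromosome 17, 46755663 to 46763712), the invariant chain of the pre-TCR, was 153-fold (115 to 207) higher in DN and the recombinase gene Rag1 (chromosome 2, 101638282 to 101649501) 139-fold (88.0 to 236). Nrarp, a Notch target, was 4.20-fold (3.66 to 4.83) higher in DN1, and Spib 1.70-fold. The medians of the progenitor and pre-TCR lists were 0.20 and -0.23 when only progenitor-like cells were compared.

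Genes of other blood lineages were higher in DN1 in most lists. All 12 NK genes were at least 2-fold higher in DN1, with a median log2 ratio of 5.69 (5.48 to 5.99), as were all 12 plasmacytoid dendritic cell genes (median 4.46), all 14 antigen-presenting myeloid genes (5.36), all 9 mast and basophil genes (6.55, or 5.32 with genes at 0 set to their bound) and all 5 measured granulocyte genes (4.11). The NK receptor gene Klre1 was 100.4-fold (61.6 to 176) higher and the chemokine gene Xcl1 74.98-fold (58.9 to 96.9). Of 12 interferon-γ-type and cytotoxic genes, 11 were at least 2-fold higher (median 5.34). Ifng, the gene of that cytokine, had 3 UMIs in DN and a ratio of 128 (43.3 to 622), whereas the granzyme gene Gzma was 1.78-fold (1.75 to 1.82) higher in DN. Of 12 ILC genes, 10 were at least 2-fold higher (median 3.60, bound 2.76), among them the arginase gene Arg1 at 29.4-fold (15.2 to 65.2). Of 8 B lineage genes, 5 were at least 2-fold higher and 1 lower (median 3.36), led by Fcrla at 74.0-fold (35.6 to 185), a gene that was also among the leading genes of plasmacytoid dendritic cell-like cells. Of 5 erythroid genes, 4 were at least 2-fold higher (median 4.71), including the carbonic anhydrase gene Car2 at 56.2-fold (48.0 to 66.3). No cluster was named granulocyte-like or erythroid-like. Mpo, Hbb-bt and Cpa3, of the granulocyte, erythroid and mast lists, were among the leading genes of a progenitor-like cluster. Of 9 stromal genes, 3 were higher and 3 lower (median 0.61, or -0.32 with cells weighted equally), with Epcam 11.8-fold (9.74 to 14.4) higher in DN.

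Cell-cycle genes were lower in DN1, with medians of -0.86 (-0.91 to -0.83) for 42 S phase genes and -1.17 (-1.23 to -1.12) for 51 G2/M genes, both at percentile 0. Of them, 15 and 33 were at least 2-fold lower and none was at least 2-fold higher. Interferon-stimulated genes had a median of 2.63 (9 of 10 at least 2-fold higher), homing and adhesion genes 2.04 (8 of 12), and TCR signal-strength genes 3.23 with a bound of 2.98 (6 of 8, with Id3 6.31-fold higher in DN). Dissociation stress genes, which rise when cells are handled, had a median of 3.80 (3.60 to 4.16), with 10 of 11 at least 2-fold higher and Fos at 56.0-fold (48.7 to 64.6). Egr1 is on both the TCR signal-strength and the stress list, and these medians do not tell TCR signal from stress. Coreceptor and double-positive stage genes had a median of -0.46 at percentile 1.31, from 4 higher and 5 lower members of 10. Themis was 105-fold (58.4 to 210.4) higher in DN and Cd69 31.3-fold (27.0 to 36.5) higher in DN1. The 4 measured Y-linked genes had a median of 0.14 (-0.04 with cells weighted equally), all within 2-fold. Over all 13430 genes the median log2 ratio was 0.10 and Spearman's correlation of the libraries across genes, which are not independent replicates, was 0.904.

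The 12 genes with the highest ratios in DN1 by the rule included the chemokine genes Ccl3 at 223-fold (117 to 489.5), Ccl6 at 128-fold (87.3 to 196) and Ccl4 at 78.2-fold (57.5 to 109). Ccl6 was among the leading genes of mast or basophil-like cells. Ccl4 was among those of a progenitor-like cluster of 609 DN1 cells, together with stress genes such as Fos and Egr1. Jchain, the joining chain of antibodies, was 209-fold (128 to 365) higher in DN1, but 2819 of its 2849 DN1 UMIs were in progenitor-like cells, where 41 UMIs were left without 10 cells with at least 10 Cd74 UMIs. The basophil protease gene Mcpt8 was 131-fold (81.5 to 225) higher, and 1700003C15Rik, a long noncoding RNA, 107-fold (68.5 to 179). Rnase6, Ctsh, S100a4 and Klrd1 were between 69.3-fold and 82.7-fold higher. The lowest was Dgkeos (chromosome 11, 89064729 to 89069098), an antisense transcript, at 0.211 CPM in DN1 and 160 CPM in DN, 757-fold (347 to 2063) higher in DN. Tubb3, Fam169b and Ccdc109b were 60.8-fold, 49.8-fold and 39.99-fold higher in DN. The imprinted noncoding RNA H19 was 29.9-fold (25.2 to 35.8) higher in DN, Aqp11 27.4-fold and Endou 26.2-fold.

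**Figure D1:**
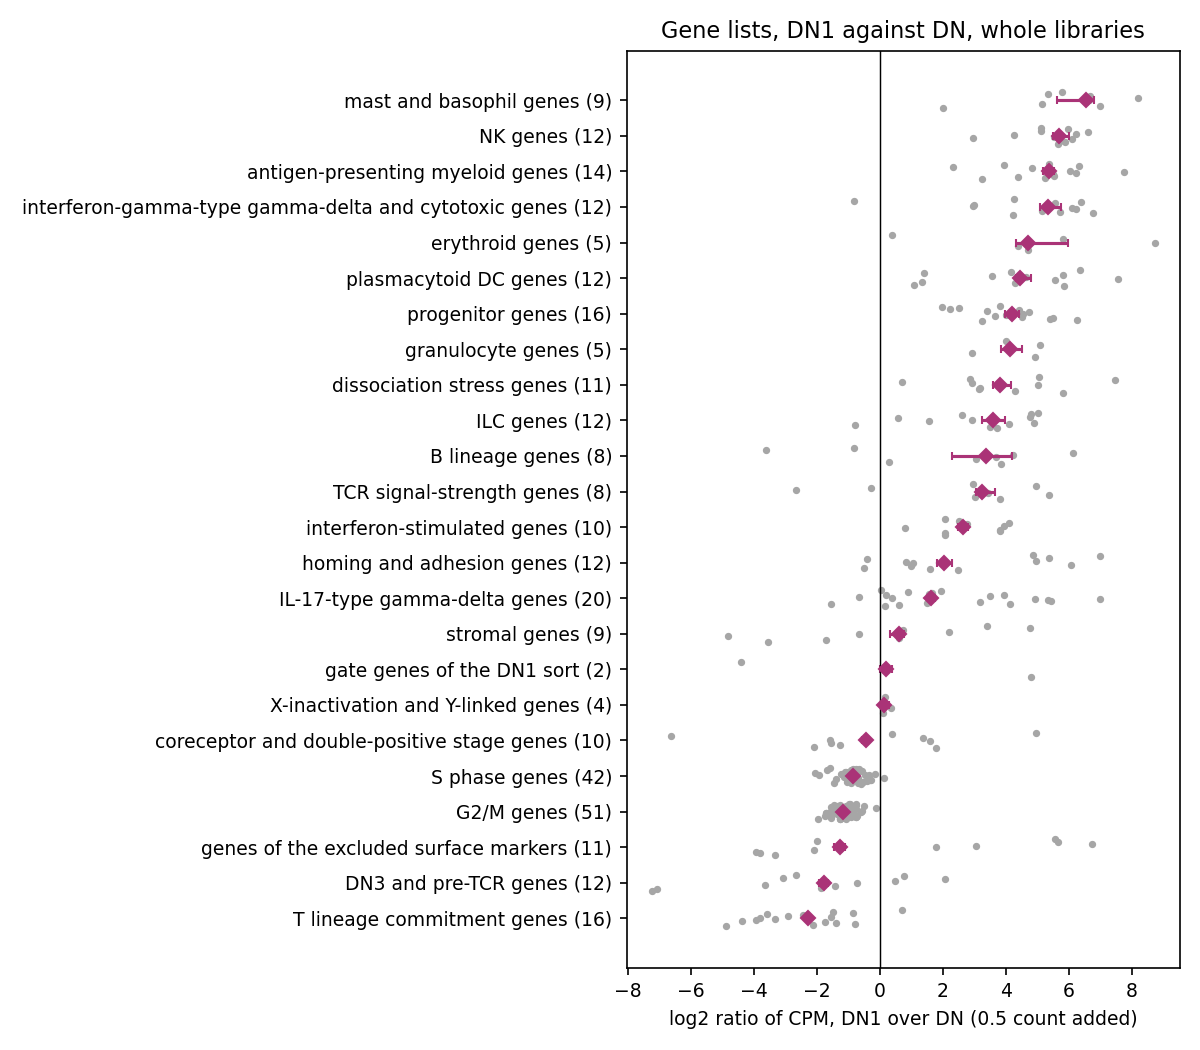
Log2 ratio of CPM in DN1 over DN (horizontal axis) for each gene list, with the number of measured members in parentheses. Diamonds are list medians with 95% counting intervals and grey points are members; the progenitor list has its median at 4.19 and the T lineage commitment list at -2.30.

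The libraries consisted largely of different cells. Early thymic progenitor-like cells made up 60.5% of DN1 (58.8 to 62.2) and 2.96% of DN (2.39 to 3.61). DN3-like cells made up 47.3% of DN (45.5 to 49.0) and 0.191% of DN1 (0.0703 to 0.416). The 6 DN1 cells had no UMI of Il2ra or Cd3d, which allows up to 39.8 CPM. In DN3-like cells of DN these genes were at 350 and 1386 CPM, so the name is uncertain for the 6 cells. A further 48.7% of DN cells (46.9 to 50.4) and 0.893% of DN1 cells lay in 4 unnamed clusters. These clusters had cell-cycle genes among their leading genes, and 3 were led by Id3, Tubb2a and Ube2c. The other, of 84 DN cells, was led by Tnfrsf8 and the mitochondrial gene mt-Nd1, with the mitotic genes Kif20a and Ect2 also among its leading genes. Its cells had a median mitochondrial share of 8.12%, against 1.85% to 1.97% in DN cells of the other 3. Their DN cells expressed Lef1 at 196 to 274 CPM, against 101 CPM in DN3-like cells of DN, a gene named under the rule for the whole libraries. Cells outside progenitor-like, DN3-like and these clusters made up 38.4% of DN1 (36.7 to 40.1) and 1.11% of DN (0.777 to 1.54). NK or NKT-like cells were the most numerous, at 17.8% of DN1 (16.5 to 19.2) and 0.382% of DN. They held Klrb1c at 559 CPM (531 to 588) in DN1, although the sort excluded surface NK1.1, against 1.39 CPM in progenitor-like cells. Of thinned cells, 65.3% of NK or NKT-like and 0.211% of progenitor-like cells of DN1 had a Klrb1c UMI, with median depths of 3950 and 10613 UMIs before thinning. Plasmacytoid dendritic cell-like cells made up 5.42% of DN1, ILC2-like cells 3.03% and conventional dendritic cell-like cells 2.68%, each under 0.1% of DN. Mast or basophil-like cells made up 1.82% of DN1 (1.38 to 2.35) and were 0 of 3144 DN cells, which allows a share of up to 0.0954%. An unnamed cluster of 4.88% of DN1 was led by the receptor gene Klra1 and the granzyme gene Gzmb. Its candidate class was αβ mature T-like, with 7 of 9 measured markers. The name was not given because the leading genes held 1 NK or NKT-like marker and no marker of the candidate class. The cluster expressed Cd3e at 670 CPM (618 to 725), against 8.67 CPM in NK or NKT-like cells. The gap was smaller for Cd3d, at 1355 against 173 CPM, and for Cd3g, at 1479 against 456 CPM. Thinning cells to 2500 UMIs before clustering gave progenitor-like cells as 47.2% of DN1, DN3-like cells as 38.7% of DN and NK or NKT-like cells as 22.4% of DN1, without a change of order between the libraries.

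**Figure D2:**
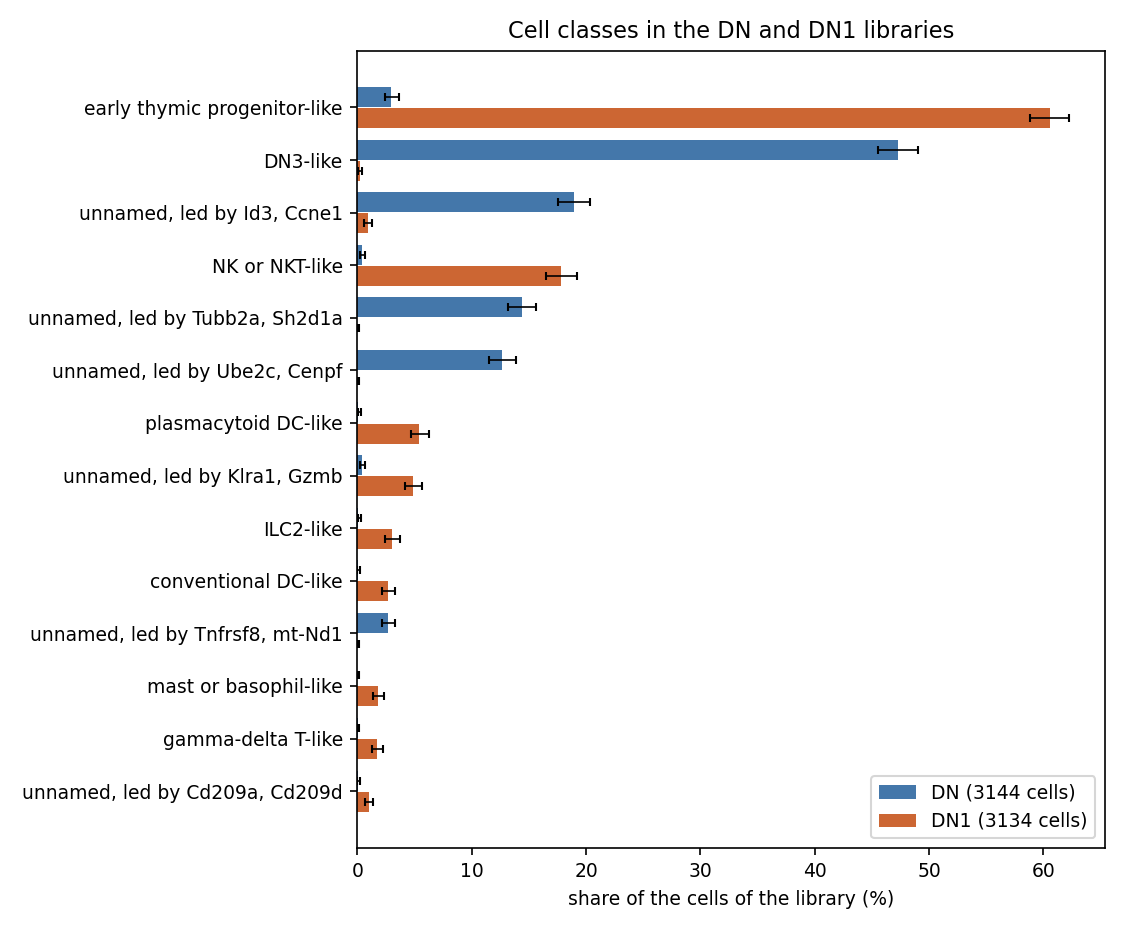
Share of the kept cells of each library (percent, horizontal axis) in each class or unnamed cluster, as bars with 95% Clopper-Pearson intervals. Early thymic progenitor-like cells make up 60.5% of DN1 and 2.96% of DN, and DN3-like cells 0.191% and 47.3%.

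Early thymic progenitor-like cells were the only class with at least 50 cells in both libraries, 1897 in DN1 and 93 in DN. Compared within this class, dissociation stress genes were higher in DN1, Il2ra was higher in DN, and most progenitor genes were within 2-fold. The stress list had a median log2 ratio of 2.12 (1.97 to 2.60) at percentile 100, with 9 of 11 genes at least 2-fold higher. The median was 3.20 over members with at least 50 UMIs, and 1.74 in the 2 clusters that held 47 and 35 of the 93 DN cells. The RNA-decay factor gene Zfp36 (chromosome 7, 28376784 to 28380253) was 23.6-fold (10.1 to 72.7) higher and the AP-1 gene Fosb (chromosome 7, 19302696 to 19310051) 16.1-fold (7.36 to 43.8). Outside the list, the transcription factor gene Klf2 was 16.8-fold (10.5 to 28.8) and the phosphatase gene Dusp1 14-fold (8.88 to 23.7) higher. Progenitor genes had a median of 0.20 (0.11 to 0.43) at percentile 99.93, above the random range of -0.22 to 0.09, with 15 of 16 within 2-fold and Flt3 3.07-fold (1.88 to 5.39) higher in DN1. T lineage commitment genes had a median of -0.96 (-1.19 to -0.56) at percentile 0, with 8 of 16 at least 2-fold lower in DN1 and 1 higher. Bcl11b was 17.9-fold (9.34 to 33.9) and Cd3e 15.7-fold (7.81 to 30.9) higher in DN, from 19 and 16 UMIs, at 20.8 and 17.5 CPM. These levels were far below the 317 and 503 CPM of the whole DN library, and the Cd3e ratio was near the 14-fold of the whole libraries, so free RNA was not excluded for these genes or for the list. Il2ra was 20.5-fold (16.3 to 25.8) higher in DN, where 32.3% of the thinned cells (22.9 to 42.7) had an Il2ra UMI, against 1.53% (1.03 to 2.19) in DN1. Cd3e, which was more abundant in the DN library than Il2ra, had a UMI in 4.30% (1.18 to 10.6) of the same DN cells. In NK or NKT-like cells of DN1 the Il2ra share was 0.914% (0.297 to 2.12) and the level 3.39 CPM (1.55 to 6.44), against 7.74 CPM (6.61 to 9.004) in progenitor-like cells of DN1. Median depths before thinning were 9359 UMIs in progenitor-like cells of DN and 10613 in those of DN1, and 3950 in NK or NKT-like cells of DN1. DN had only 12 NK or NKT-like cells, too few for a background share. Without cells that had an Il2ra UMI before thinning the median of the commitment list was -0.22, and with members of at least 50 UMIs it was -0.53. The other lowest genes by the rule were Ctsl, Cd74, H2-Ab1 and Fabp5, at 13.3-fold, 4.23-fold, 2.74-fold and 2.41-fold higher in DN. Without 3 DN and 10 DN1 cells that had a Krt8 UMI or at least 10 Cd74 UMIs, the DN1 over DN ratios of Ctsl and H2-Ab1 were 1.39 (0.722 to 3.07) and 1.37 (0.878 to 2.25), intervals that include 1, and that of Fabp5 was 0.724 (0.640 to 0.822). Cd74 was not compared without those cells because its own count chose them. Jchain, at 131 CPM in DN1 and 0 in DN, was at least 39.8-fold higher with those cells; without them it was at 1.91 CPM, below what 0 DN counts can tell apart.

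Among the remaining lists within progenitor-like cells, medians were -0.19 for S phase, -0.48 for G2/M and -0.66 for granulocyte genes. These 3 turned positive in the 2 clusters that held most DN cells, at 0.054, 0.11 and 0.17. Medians were 0.28 for interferon-stimulated, -0.06 for IL-17-type, -0.23 for DN3 and pre-TCR, -0.35 for ILC and -0.09 for antigen-presenting myeloid genes. TCR signal-strength genes, which share Egr1 with the stress list, had a median of 1.98, with 5 of 8 at least 2-fold higher and Cd69 at 13.2-fold (7.86 to 24.2). Of this list, Egr1, Nr4a1 and Cd69 were leading genes of the progenitor-like cluster of 609 DN1 cells, as were the stress genes Fos and Zfp36. The median therefore does not tell TCR signal from stress. Stromal genes had a median of -2.41, with Krt8 at 63 UMIs in DN and 0 in DN1. Krt8 was not compared without the cells left out above because its own UMIs chose them. Lists with several members at 0 in DN gave medians that turned negative when those members were set to their bound, in coreceptor (1.18, bound -0.42), NK (0.69, bound -0.60), B lineage (0.99, bound -1.03), mast and basophil (0.88, bound -0.06), erythroid (0.72, bound -0.12), plasmacytoid dendritic cell (0.08, bound -0.08) and interferon-γ-type genes (0.20, bound -0.59). Homing genes had a median of 0.28 (bound 0.08, or -0.25 with 5 counts added). The median of genes of the excluded markers was -1.02 (bound -1.26) and that of the 4 Y-linked genes -0.03.

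**Figure D3:**
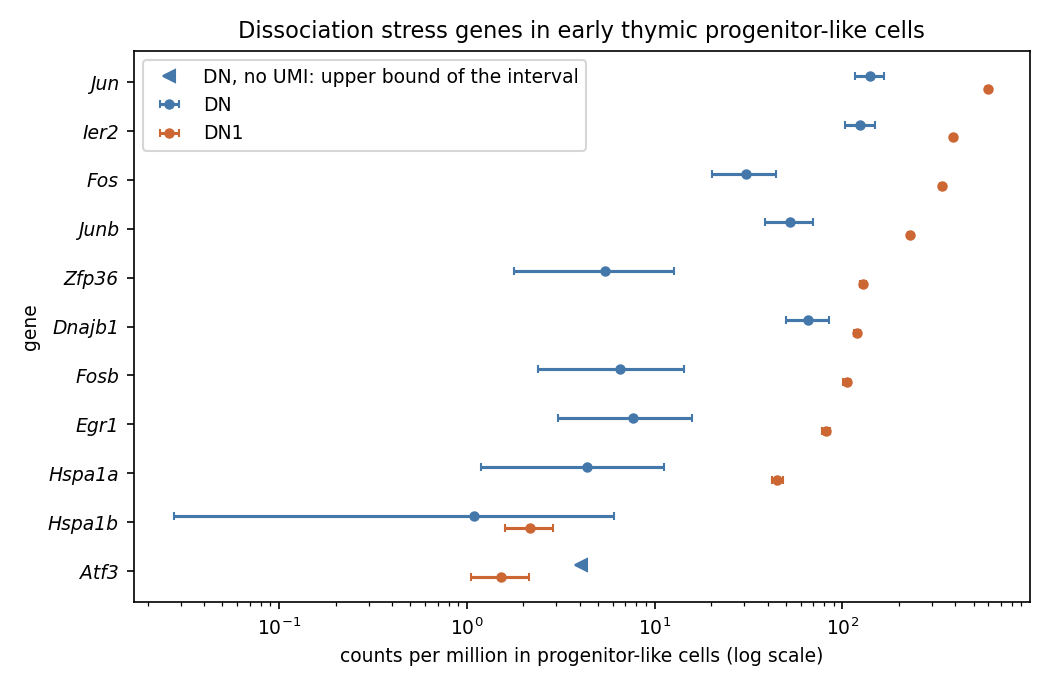
CPM (log scale) of dissociation stress genes in early thymic progenitor-like cells, as points with exact 95% Poisson intervals for DN (93 cells) and DN1 (1897 cells). The arrow marks the upper bound for Atf3, which had no UMI in DN; Zfp36 is 23.6-fold and Fosb 16.1-fold higher in DN1.

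Some genes of IL-17-type γδ T cells were highest in 2 small groups of DN1 cells, and others in other cells. Over the whole libraries, 12 of 20 measured IL-17-type genes were at least 2-fold higher in DN1 and 1 lower, with a median log2 ratio of 1.61 (1.54 to 1.73) at percentile 99.98. Their median was -0.06 when only progenitor-like cells were compared. The chemokine receptor gene Ccr6 had 54 UMIs in DN1 and none in DN, at least 21.1-fold, and Il1r1 was 43.1-fold (19.5 to 119) higher. Rorc, which encodes RORγ, was 2.96-fold (2.39 to 3.70) and 5830411N06Rik 1.59-fold (1.18 to 2.15) higher in DN. None of the 16 γ and δ TCR genes on the fixed list is in the tables, so receptor expression was not measured. Of the 18 IL-17-type genes with at least 30 UMIs, 4 had their highest level among DN1 groups of at least 20 cells in the γδ T-like class, 8 in 28 cells of an unnamed cluster and 6 elsewhere. These 2 groups together held most of the DN1 UMIs of 4 genes, Rorc, Blk, Ccr6 and 5830411N06Rik. Most DN1 UMIs of Sox13 (419 of 458) and Il1r1 (193 of 221) were in progenitor-like cells, and 131 of 181 of Cd163l1 in NK or NKT-like cells.

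The γδ T-like class held 54 DN1 cells, 1.72% (1.30 to 2.24), and 1 DN cell. In its DN1 cells the kinase gene Blk was at 282 CPM (231 to 341) and Ccr6 at 79.1 CPM (53.4 to 113). Other members were at similar or higher levels in further DN1 cells. Ccr2 was at 285 CPM (234 to 344), against 375 CPM in NK or NKT-like, 368 CPM in ILC2-like and 358 CPM in mast or basophil-like cells. Il7r was at 361 CPM (303 to 427), against 429 CPM in ILC2-like cells, and Zbtb16 at 60.7 CPM (38.4 to 91.0), against 54.0 CPM (39.9 to 71.4) in the cluster led by Klra1. Lmo4 and Rora were highest in ILC2-like cells, at 947 and 352 CPM. The factor gene Sox13 was at 5.27 CPM (0.639 to 19.1). The other group was 28 DN1 cells in an unnamed cluster that was otherwise made of 595 DN cells and led by Id3 and Ccne1. These 28 cells expressed Sox13 at 311 CPM (214 to 436), Blk at 649 CPM (505 to 822), Maf at 461 CPM (341 to 610), Rorc at 301 CPM (206 to 425) and 5830411N06Rik at 424 CPM (309 to 567), against 10.5, 4.6, 2.05, 20.3 and 6.15 CPM in the DN cells of the cluster. This clustering did not leave out those genes. In the clustering without IL-17-type and γδ genes they were at 109, 235, 176, 136 and 159 CPM in 57 DN1 cells. These were the DN1 cells of the γδ T-like cluster with the higher Sox13 level. The markers behind that name include Sox13, Blk, Maf and 5830411N06Rik, so the choice favours their levels. The 28 cells had no UMI of Ccr6, Ccr2, Il1r1 or Zbtb16, which allows up to 28.2 CPM, and 3 UMIs of Il7r, at 28.2 CPM (5.82 to 82.5). In the 57 cells, Ccr6 also had no UMI. Zbtb16 had 11 UMIs there, at 36.5 CPM (18.2 to 65.3), and Il7r was at 106 CPM (72.6 to 150), so these 2 levels depended on the clustering. Of the 28 thinned cells, 53.6% (33.9 to 72.5) had a Sox13 UMI, against 4.49% in progenitor-like cells of DN1, 5.45% in DN3-like cells of DN and 0% in NK or NKT-like cells of DN1, at median depths of 3399, 10613, 5512 and 3950 UMIs before thinning. Chosen after their values were seen, Cd24a, a surface marker of immature thymocytes, was at 188 CPM (115 to 291) in the 28 cells and at 0 in the γδ T-like cells (up to 7.91), and the thymic homing receptor gene Ccr9 at 1807 CPM (1561 to 2082) and 13.2 CPM. In the 57 cells they were at 119 and 633 CPM. In DN1 cells without UMIs of at least 3 of Sox13, Blk, Maf, Rorc and 5830411N06Rik they were at 189 and 49.0 CPM, so Cd24a was not raised in the 28 cells. The 28 cells and the γδ T-like cells both expressed Cd3e, at 828 CPM (664 to 1021) and 670 CPM (590 to 757).

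UMIs of at least 3 of the 5 genes Sox13, Blk, Maf, Rorc and 5830411N06Rik, a set chosen after the levels of these genes were seen, were found, before thinning, in 48 DN1 cells, 1.53% (1.13 to 2.03), and in 11 DN cells, 0.350% (0.175 to 0.625), a ratio of 4.38 (2.24 to 9.35). Shuffling each gene over the cells of a library gave a mean of 6.07 and at most 17 such cells in DN1, and a mean of 4.63 and at most 12 in DN, where the number of cells alone lay within the shuffled range. In the clustering without IL-17-type and γδ genes, 11 DN cells shared a cluster with 57 DN1 cells, and 6 of the 11 had UMIs of at least 3 of the genes. This cluster was picked as the γδ T-like cluster with the higher Sox13 level, and its name rests on markers that include Sox13, Blk, Maf and 5830411N06Rik. This choice favours that count and the levels of these genes in its cells. These 11 DN cells expressed Sox13 at 286 CPM (160 to 472), Blk at 153 CPM (65.9 to 301) and Maf at 229 CPM (118 to 400), against 14.4, 3.78 and 1.17 CPM in all DN cells. The 57 DN1 cells expressed these genes at 109 CPM (75.3 to 154), 235 CPM (184 to 297) and 176 CPM (132 to 230). Of the 48 DN1 cells, 25 were among the 28 cells above and 17 in the γδ T-like class, an overlap that the choice of genes favours. Outside the naming rule, the cytokine gene Il17a had no UMI in the 48 DN1 cells or the 11 DN cells with at least 3 of the genes. Exact Poisson upper limits were 12.2 and 27.1 CPM. Il23r had 4 UMIs in the 48 DN1 cells, at 13.2 CPM (3.61 to 33.9), and none in those DN cells. The share of the γδ T-like class and its Sox13 level depended on the clustering: the share lay between 0% with 15 components and 3.94% with doublets kept, and Sox13 was at 335 CPM at resolution 0.5, where the class was 0.830% of DN1.

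**Figure D4:**
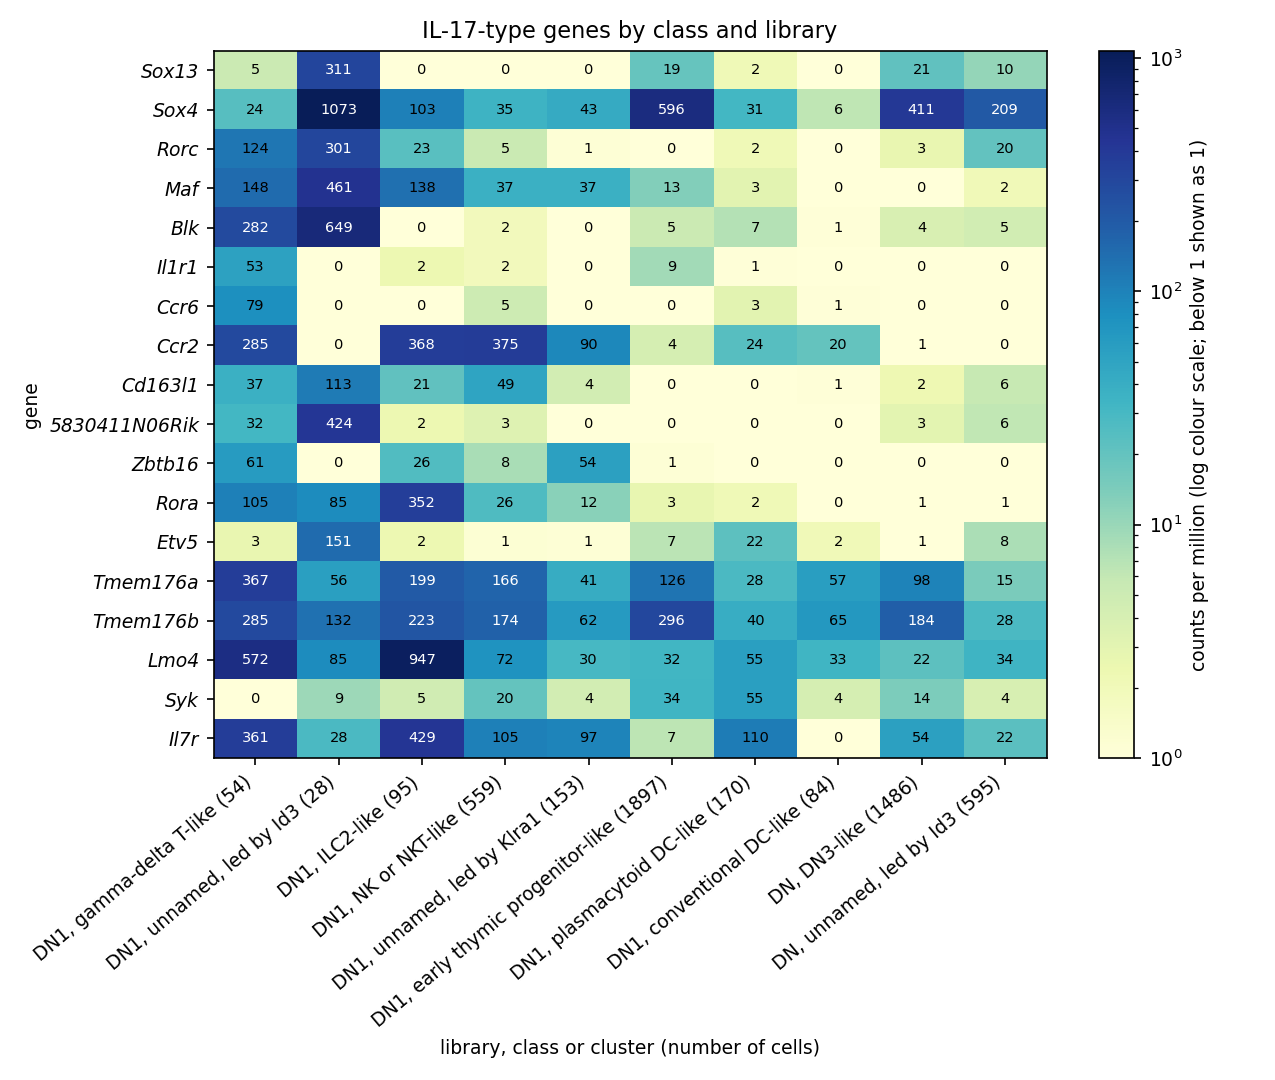
CPM (numbers in cells and log colour scale) of IL-17-type genes with at least 30 UMIs, in classes and unnamed clusters of DN1 and DN, with the number of cells in parentheses. Sox13 is at 311 CPM in 28 DN1 cells of an unnamed cluster led by Id3 and at 5.27 CPM in the 54 γδ T-like cells of DN1.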

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

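Barcodes with more than 10% mitochondrial UMIs were left out of the comparisons, except under the alternative that kept every barcode, and they drew attention because both libraries held them well above the share that a count of 0 allows. They made up 4.29% of DN barcodes (143 barcodes, 3.62 to 5.03) and 0.533% of DN1 barcodes (17 barcodes, 0.311 to 0.853). In DN they carried Ptcra at 267 CPM and Rag1 at 99.4 CPM, against 258 and 88.2 CPM in kept DN cells. The activation marker gene Tnfrsf8 was at 50.6 CPM against 12.6, the costimulatory receptor gene Cd28 at 144 CPM against 52.0, and Mki67, a marker of dividing cells, at 329 CPM against 134. The 17 DN1 barcodes also held Mki67 at 217 CPM (12 UMIs) against 40.2 in kept DN1 cells, Cd28 at 72.4 CPM (4 UMIs) against 17.4 and Cd34 at 380 CPM (21 UMIs) against 289. These genes were chosen after their values were seen.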

How the results depend on the processing

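No paired analysis was possible because each group has 1 library. The alternatives that left out IL-17-type, stress or top-scoring doublet genes or cells, cells with an Il2ra, Krt8 or high Cd74 count, all clusters but 7 and 10, or that counted thinned cells for the gene set of 5, were chosen after the data were seen. The cause of the shifts below was not tested unless named. Of the main results under all alternatives, 119 values stayed within the counting interval, 42 moved beyond it without reversing and 1 reversed. Of the other values, 442 stayed, 143 moved and 20 reversed. The ratio of Cd44 stayed between 24.9 and 29.0 and the progenitor median within progenitor-like cells between 0.12 and 0.30.

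With only progenitor-like cells, which removes differences between classes but not within this class, medians were 0.20 for progenitor, -0.96 for T lineage commitment, -0.23 for DN3 and pre-TCR and 0.69 for NK genes, and reversed to -0.058 for IL-17-type, -0.35 for ILC, -0.094 for antigen-presenting myeloid, -0.66 for granulocyte, -2.41 for stromal, -1.86 for gate, -0.030 for X- and Y-linked and 1.18 for coreceptor genes. With cells weighted equally, the Il2ra ratio was 29.4 and medians were 3.84 for progenitor, -1.88 for T lineage commitment, -2.05 for DN3 and pre-TCR and 1.48 for IL-17-type genes, and reversed to -0.32 for stromal, -0.037 for X- and Y-linked and -0.12 for gate genes. TMM factors gave -2.36 for T lineage commitment genes. Members with at least 50 UMIs gave 1.52 for IL-17-type genes, and within progenitor-like cells -0.53 for T lineage commitment and 3.20 for stress genes. TMM and equal weights moved the median of all genes by under 0.1 (-0.07 each).

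Within progenitor-like cells, 5 added counts turned lists whose members had few or no DN UMIs: -1.84 for B lineage, -0.92 for NK, -0.95 for coreceptor, -0.30 for erythroid, -0.25 for homing and -0.65 for mast and basophil genes, and the stricter cell filter gave -0.0073 for the last. Leaving out cells with an Il2ra UMI gave -0.22 for T lineage commitment genes. Clusters 7 and 10 alone gave 1.74 for stress genes and reversed G2/M (0.11), S phase (0.054) and granulocyte genes (0.17).

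Thinned cells gave shares of 38.7% for DN3-like cells in DN, and in DN1 47.2% for progenitor-like, 22.4% for NK or NKT-like and 0.934% for γδ T-like cells; resolution 2 gave 43.8% for DN3-like cells and 15 components 19.3% for NK or NKT-like cells. The γδ T-like share of DN1 was 0 with 15 components, 0.830% at resolution 0.5, 0.841% with the stricter filter, 2.44% without the top 3% of doublet scores, 2.49% without cell-cycle genes, 2.55% at resolution 2 and with sort genes left in, 3.48% with every barcode, 3.57% without IL-17-type and γδ genes and 3.94% with doublets kept. In that class Sox13 was at 51.0 CPM with every barcode, 335 CPM with the stricter filter and at resolution 0.5, 42.0 CPM with doublets kept and 73.3 CPM at resolution 2. Blk was at 691 CPM with the stricter filter and at resolution 0.5, 208 CPM with doublets kept and 366 CPM at resolution 2. The share of cells with 3 of the 5 genes was 0.773% in DN1 and 0.127% in DN after thinning, which lowers detection by construction, and stayed within its interval under the other alternatives. Depth limits genes with few UMIs in the 93 DN progenitor-like cells, where a count of 0 allows 3.28 CPM.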

Other observations

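The tests of Hbb-bt, of doublets and of free RNA for the Sox13-expressing cells were chosen after those results were seen, as were the clusters left out of the stress comparison and the genes in the next paragraphs.

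Progenitor-like cells of DN1 fell into 5 clusters that differed in their leading genes. The largest, of 609 DN1 cells and no DN cell, was led by immediate-early genes such as Fos, Egr1 and Zfp36. These are on the stress list, so handling was not excluded as the source of this cluster. A cluster of 171 DN1 and 5 DN cells was led by the interferon-stimulated genes Ifit1, Ifit3 and Isg15. A cluster of 386 DN1 and 6 DN cells had Cd34, Flt3 and Hoxa9, genes of early progenitors, among its leading genes. The remaining clusters, which held 47 and 35 DN cells, had Mpo and Kit, and the histone gene Hist1h2ap and Hoxa9, among theirs. The myeloid granule gene Mpo was at 384 CPM (376 to 392) in progenitor-like cells of DN1 and 342 CPM in those of DN. The granule protease genes Elane, Prtn3 and Ctsg together reached at least 100 UMIs in 8 DN1 cells and 1 DN cell.

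NK or NKT-like cells of DN1 carried the granzyme genes Gzmc at 979 CPM (942 to 1018) and Gzma at 4407 CPM, the NK receptor gene Ncr1 at 537 CPM and Il7r at 105 CPM. The unnamed cluster led by Klra1 carried the checkpoint receptor gene Pdcd1 at 116 CPM (94.6 to 140.0), against 6.78 CPM in NK or NKT-like cells, and the chemokine receptor gene Cxcr3 at 221 CPM. A cluster of 31 DN1 and 2 DN cells was led by Cd209a and Cd209d. Its candidate class was plasmacytoid dendritic cell-like, with 11 of 13 markers, but the naming conditions were not met.

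Immediate-early genes were higher in progenitor-like cells of DN1, with a median log2 ratio of 2.12 for the stress list. Leaving out all cells with an Il2ra UMI left it at 2.19 (1.88 to 2.66), which argues against cells with detected Il2ra as the source. CD25-positive cells without an Il2ra UMI were not removed by this step. Even of DN3-like cells of DN, 79.3% had an Il2ra UMI before thinning. Over the other 9 clusters held by both libraries, the list was also higher in DN1, with a median of 1.76 (1.47 to 2.14). The highest summed ratio, 9.83-fold, came from the cluster of 28 DN1 and 595 DN cells, whose cells differed between the libraries in type and depth, and without it the median was 1.41 (1.04 to 1.72). Without the cluster of 6 DN1 and 494 DN cells as well it was 1.05 (0.873 to 1.62). The remaining 7 clusters held only 1 to 12 DN cells each, with 4 to 47 stress UMIs, and in them the summed ratio was between 1.24-fold, with an interval that includes 1, and 5.33-fold. Handling of the whole DN1 library may therefore account for part of the difference. A difference between the gated populations themselves stays open and untested, since each gate has 1 library.

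Hbb-bt, an adult β-globin gene, was at 451 CPM in progenitor-like cells of DN1 and 549 CPM in those of DN, with a UMI in 15.5% (13.9 to 17.2) and 17.2% (10.2 to 26.4) of thinned cells, against 0.914% in NK or NKT-like cells of DN1. Median depths of these groups before thinning were 10613, 9359 and 3950 UMIs. Erythroid cells or their RNA would bring the other adult globins, but Hbb-bs, Hba-a1 and Hba-a2 together had 0.00349 (0.00242 to 0.00488) UMIs per Hbb-bt UMI, and the sort excluded Ter119. Free RNA shared by all cells would give similar levels across types, but Hbb-bt was 133-fold (70.0 to 291) higher in progenitor-like than in NK or NKT-like cells of DN1. Expression of Hbb-bt by the progenitor-like cells is a candidate explanation, found and tested on the same data. Assignment of reads between the adult β-globin paralogs was not tested.

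Sox13-expressing cells with other IL-17-type γδ genes were present although both sorts excluded surface TCRδ. To keep those genes from grouping the cells, the tests used a clustering without them. In it, 57 DN1 and 11 DN cells formed 1 of 2 γδ T-like clusters, the one with the higher Sox13 level. The name γδ T-like still rested on markers that include Sox13, Blk, Maf and 5830411N06Rik. The choice of cluster therefore favours high levels of these genes. Of the 57 cells, 25 had UMIs of at least 3 of the genes Sox13, Blk, Maf, Rorc and 5830411N06Rik, and 17 had a Sox13 UMI. Doublets with a progenitor-like cell, at a median of 10613 UMIs in DN1, would tend to exceed the library median. The median of the 57 cells was 0.522 (0.479 to 0.602) of that of DN1, 4167 against 7981. That of the 17 cells with a Sox13 UMI was 0.436 (0.387 to 0.491). Doublets of 2 smaller cells need not exceed the library median, so they were not tested by it. NK or NKT-like and ILC2-like cells of DN1 had medians of 3950 and 4108 UMIs. Free RNA is argued against by the thinned share of cells with a Sox13 UMI, which was 9.22 (4.95 to 16.1) times that of the other DN1 cells, 26.3% against 2.85%. As the cluster was picked for Sox13, cells with a Sox13 UMI were shuffled over all DN1 cells 10000 times, and the highest share of any of the 14 clusters with at least 20 cells was then 19.4%. The other γδ T-like cluster, of 53 thinned DN1 cells, had no cell with a Sox13 UMI. Whether cells with surface TCRδ or TCRβ passed the sort or the cells lacked surface receptor cannot be told apart. The matrices hold no TCR gene and measure 0 of the 16 γ and δ TCR genes, so γδ identity itself was not tested.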
